A study of Rattus norvegicus with 12 samples.

How the data were processed

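RNA was sequenced from 12 rat libraries in 4 groups of 3. Per the labels, the animals were male SAS Fischer rats of 200 to 225 g. Hematoma from a femoral defect of 0.5 mm (normal healing), 1.5 mm (delayed healing) or 5.0 mm (nonunion) made up 3 groups, and the piece of femur taken out at surgery (preOP) made up the other. Per the labels, RNA was extracted with Trizol and 1 ug of total RNA went into the Illumina TruSeq RNA kit. The labels do not say whether the libraries come from separate animals, so p-values here measure the spread between samples.

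The authors prepared reads with bcl2fastq 1.8.4, FastQC and Trimmomatic and quantified transcripts with Salmon. Their stated genome build was rn6, and versions of the other tools are not given in the sources used here. Each deposited file holds 1 library with 18321 RefSeq transcripts, of which 17648 are protein-coding and 673 are non-coding entries. Per the file headers, the values are estimated counts (expected counts of reads per transcript, not scaled), TPM (transcripts per 1e6, after division by effective length) and effective transcript lengths in bases. The deposited TPM were not used for tests. The deposited effective lengths were used to compare fragment lengths and in 1 alternative.

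Estimated counts were rounded and summed by gene symbol from a RefSeq annotation, which gave names only. This matched 17367 transcripts to 16425 symbols. The 954 unmatched transcripts were kept as single features, for 17379 features in all. No coordinates were used. Totals per library ran from 16808993 to 24325162 estimated reads. A gene with no reads in a library is bounded by 3 reads, which is 0.12 to 0.46 counts per 1e6 reads (CPM) depending on the library. A ratio against a group with 1 to 3 reads is given from pooled reads with an exact binomial 95% interval. These bounds and intervals cover counting error only.

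Differential expression was tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood F-tests after TMM scaling and filterByExpr by group. The 3 comparisons among hematomas used 1 fit of 9 libraries with 6 residual degrees of freedom and 12474 genes. Comparisons with preOP used 1 fit of all 12 libraries with 8 residual degrees of freedom and 12846 genes. The mean hematoma weighs the 3 hematoma groups equally. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 with no fold threshold. All tests were two-sided. CPM values are TMM-scaled, and errors are SD over 3 libraries or an approximate standard error (SE) of the log2 fold change. This SE is the absolute log2 fold change divided by the square root of the F statistic.

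In all, 34 gene lists for cell types and pathways were tested with camera in limma 3.58.1 at a preset correlation of 0.01, for lists with at least 5 measured members. Each list was tested again with its correlation estimated from the data, and with fry. The comparisons, tests of genes and lists, the lists and the rule for named genes were fixed before the data were examined.

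The rule took the 6 largest changes each way among called genes with non-overlapping libraries and a mean of at least 5 CPM in the higher group. It also took up to 4 called members per list, and up to 2 abundant members where fewer than 2 were called. The report names a part of the genes the rule selects, and some selected genes are not reported. That part, and the uncalled genes named for nonunion against delayed, were picked after their values were seen. The alternatives follow every called gene of the rule and each uncalled gene named for nonunion against delayed.

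The method was tested on simulated data, with 200 changed genes planted in libraries drawn at the fitted spread. For delayed against normal, 62.1% of 8-fold, 9.0% of 4-fold and 1.5% of 2-fold changes were recovered. For the mean hematoma against preOP these shares were 81.8%, 67.2% and 14.9%. False calls made up 3.5% to 5.9% of calls. Where more than 200 genes change, the adjusted threshold is less strict. The recovered shares can then be too low, as for delayed against normal (889 calls) and the mean hematoma against preOP (5212 calls).

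Alternatives fixed before the data were examined were DESeq2 size factors, no filter on low counts, a replicate block, DESeq2 1.42.0, limma-voom, a minimum fold, other sets of libraries in the fit, and leaving out each library in turn. Added after seeing the data were fits without ribosomal RNA, without delayed 2 and nonunion 2, without the normal libraries, with effective lengths as offsets, with library weights in voom, and with robust = TRUE in edgeR. No library was left out of the reported values. Pairs of libraries with identical counts numbered 0.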

Results

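Transcript levels were measured by RNA sequencing in the hematoma that fills a femoral defect and in the femur piece removed at surgery. The hematomas came from defects of 0.5 mm (normal healing), 1.5 mm (delayed healing) and 5.0 mm (nonunion), with 3 libraries per group and 3 preOP femur libraries. Totals ranged from 16979305 to 18890622 estimated reads in normal, 18721435 to 22283313 in delayed, 18587661 to 24325162 in nonunion and 16808993 to 19158121 in preOP. Between 11442 and 12444 genes per library had at least 10 estimated reads.

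The preOP femur pieces carried 15.66% to 23.98% of reads on globin genes, against 0.03% to 2.96% in the hematomas. Library nonunion 2 carried 72.17% of its reads on ribosomal RNA, against at most 1.74% elsewhere, and a further 8.22% on 2 unnamed transcripts linked to it, which together left 4.77 M (1e6) other reads. In the same library the adipocyte gene Fabp4 stood at 4430 CPM, against at most 508 CPM in the other hematomas. Library delayed 2 carried 8.41% of its reads on 20 skeletal muscle genes, against at most 0.92% in the other hematomas. The normal files also differed from all others in form. A decimal point stood in 16.82% to 18.1% of their read numbers and in 100% elsewhere, and the median gap between transcript length and effective length was 157.2 to 191.6 bases against 194.3 to 254.6. This split holds samples of 1 group only, so no comparison with normal can be recomputed within a batch, and batch and group cannot be told apart there.

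**Figure D1:**
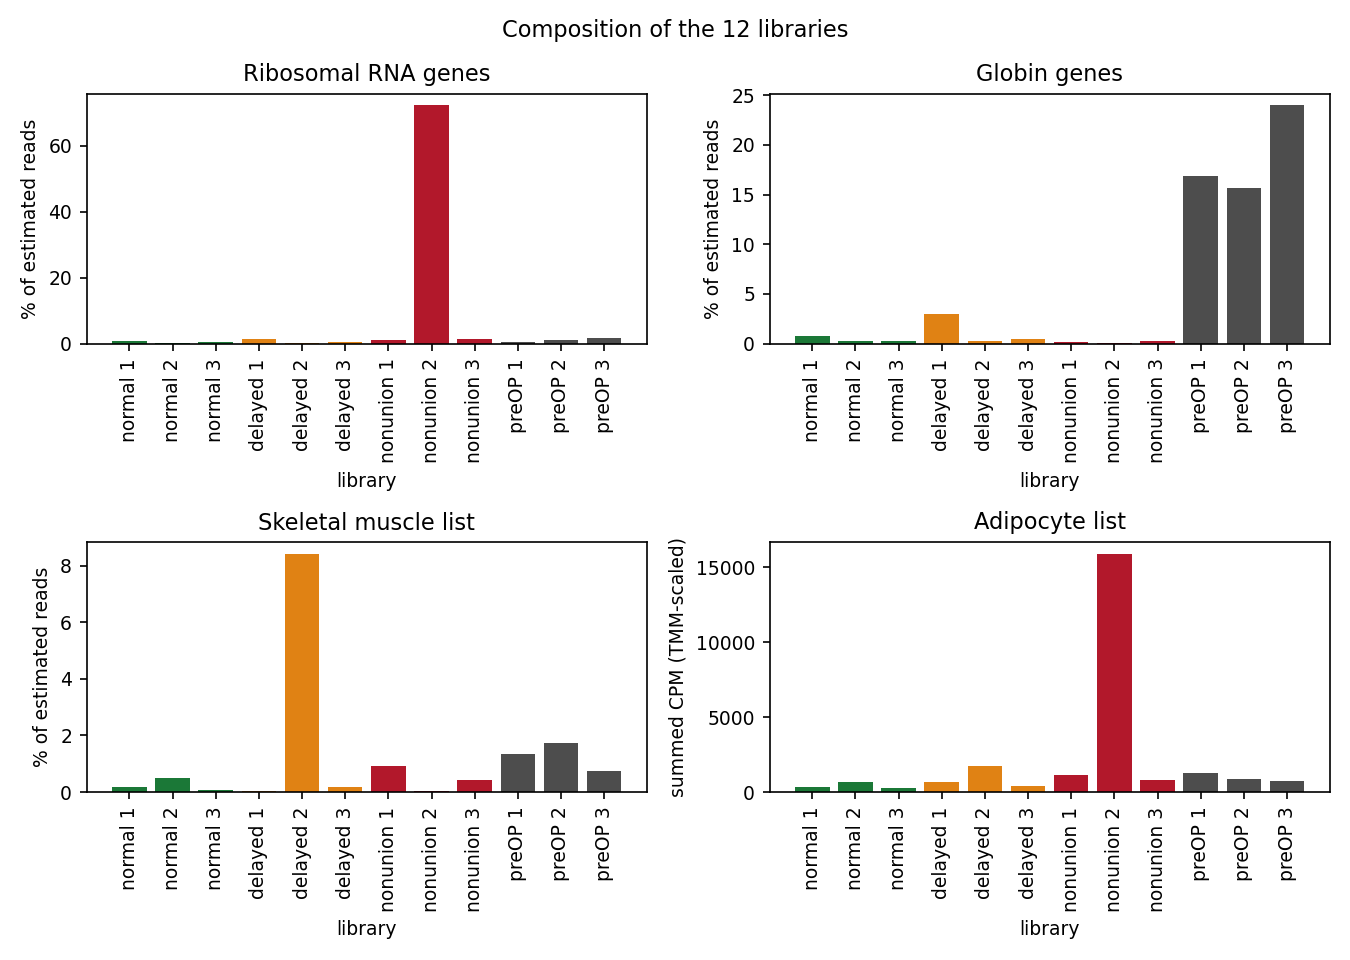
Bars show each library's share of estimated reads (%) on ribosomal RNA, globin and skeletal muscle genes, and its summed CPM over the adipocyte list. Nonunion 2 stands out for ribosomal RNA (72.17%), delayed 2 for muscle (8.41%) and the 3 preOP libraries for globin (15.66% to 23.98%).

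The first principal component held 42.7% of the variance of log2 CPM and set the preOP libraries (scores of 126.6 to 128.7) apart from the hematomas. The second held 19.1% and set the 3 normal libraries (59.4 to 77.2) apart from the others. Nonunion 2 and delayed 2 lay away from the other libraries of their groups.

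**Figure D2:**
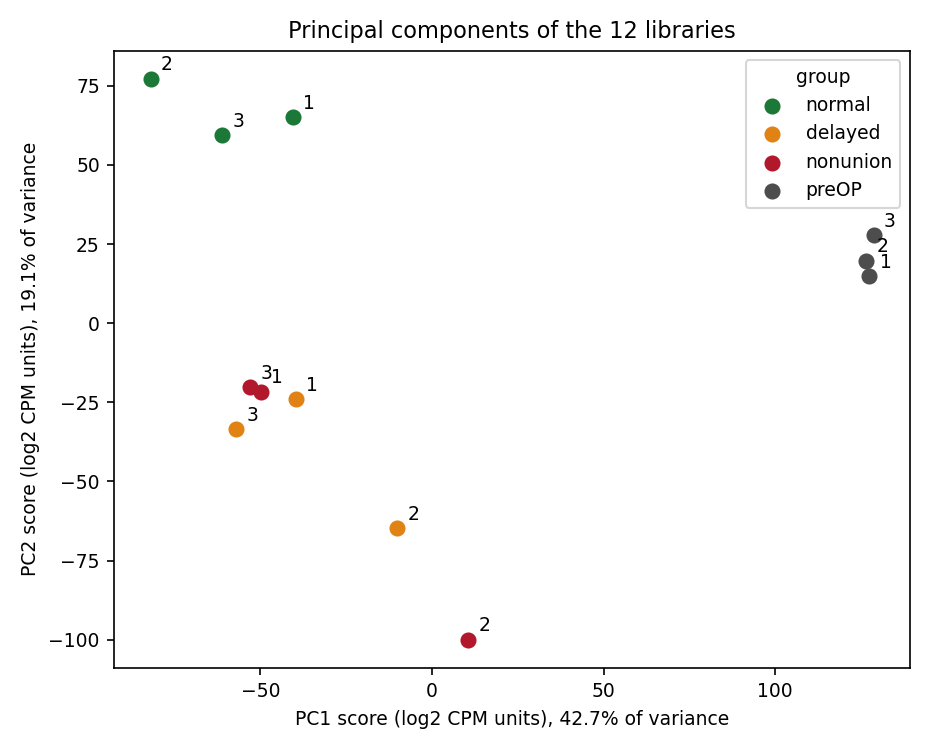
Points are the 12 libraries on the first and second principal components of log2 CPM (42.7% and 19.1% of variance), coloured by group and numbered by replicate. The preOP libraries lie at 126.6 to 128.7 on the first and the normal libraries at 59.4 to 77.2 on the second.

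Delayed against normal asks how the hematoma of a 1.5 mm defect differs from that of a 0.5 mm defect that heals. Genes of mineralising bone were far lower in delayed hematomas. Ibsp, which encodes bone sialoprotein, averaged 987 ± 171 CPM (SD, n = 3) in normal and 3.33 ± 0.706 CPM (SD, n = 3) in delayed, and fell by 8.24 on the log2 scale (SE 0.46, edgeR adjusted p = 0.00022). Alpl, the alkaline phosphatase of mineralisation, went from 323 ± 40.0 to 3.14 ± 1.63 CPM (SD, n = 3 each) and fell by 6.71 (SE 0.55). Bglap, encoding osteocalcin, fell by 5.97 (SE 0.39), and the osteoblast transcription factor Dlx5 fell by 5.82 (SE 0.52). In the other direction, Vegfa, the main angiogenic growth factor, rose by 2.46 (SE 0.46), from 105 ± 27.7 to 586 ± 187 CPM (SD, n = 3 each).

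In all, 889 of 12474 genes were called, 334 higher and 555 lower in delayed. In a fit without delayed 2 and nonunion 2, a choice made after seeing the data, 2056 genes were called, 962 higher and 1094 lower, and 843 of the 889 were among them.

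Of 13 measured osteoblast and bone matrix genes, 7 fell, 0 rose and 6 did not pass, with 9 lower when adjusted over the list alone and a median log2 fold change of -3.96. Camera gave an adjusted p of 5.9e-21 for this list, and adjusted p = 0.0073 with an estimated correlation. Of 8 osteocyte genes 6 fell, also 6 adjusted over the list alone (camera adjusted p = 2.1e-10; adjusted p = 0.035 with an estimated correlation). They included the matrix phosphoglycoproteins Mepe (-8.79, SE 0.75) and Dmp1 (-7.55, SE 1.20) and the Wnt inhibitor Dkk1 (-4.15, SE 0.61). Of 12 chondrocyte and cartilage matrix genes 8 fell, and 10 adjusted over the list alone (median -4.25; camera adjusted p = 2.1e-12; adjusted p = 0.038 with an estimated correlation). Among them were the fibrillar collagen gene Col11a2 (-5.36, SE 0.54), Comp (-4.62, SE 0.50), the chondrocyte transcription factor Sox9 (-2.74, SE 0.43) and the link protein gene Hapln1 (-7.76, SE 1.35). For these 3 lists the adjusted p with an estimated correlation was 0.06, 0.1 and 0.061 without delayed 2 and nonunion 2, while 8, 6 and 11 members were called lower. Of 13 osteoclast genes 0 were called, with 0 adjusted over the list alone (median -0.60; camera adjusted p = 0.9).

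**Figure D3:**
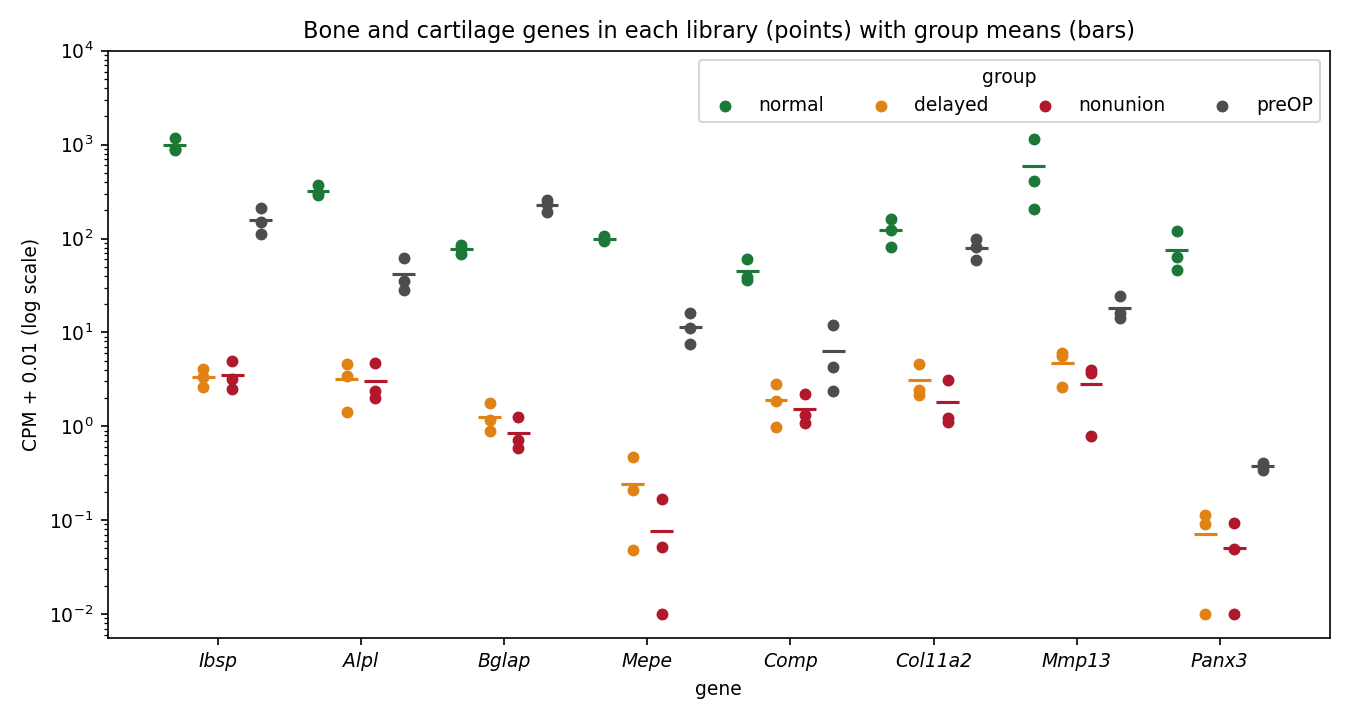
Points show CPM plus 0.01 on a log scale in each of 12 libraries for 8 bone and cartilage genes, with short bars at the group means (n = 3 per group). Ibsp averaged 987 CPM in normal, 3.33 in delayed, 3.52 in nonunion and 158 in preOP.

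Some neutrophil granule and eosinophil genes fell too. Of 10 neutrophil granule precursor genes 4 fell, and 8 adjusted over the list alone (median -3.87; camera adjusted p = 1.8e-06; adjusted p = 0.51 with an estimated correlation). They included the defensin gene Np4 (-6.76, SE 1.06), Lcn2 (-6.08, SE 1.21) and cathepsin G, Ctsg (-4.91, SE 1.06). Normal 1 carried Np4 at 1120 CPM, against 177 and 257 CPM in normal 2 and 3. The mast cell and eosinophil list held 3 fallen genes and 1 that rose of 13 (camera adjusted p = 0.0052; adjusted p = 0.58 with an estimated correlation), with 4 lower and 1 higher adjusted over the list alone. Eosinophil peroxidase, Epx, fell by 6.26 (SE 0.84) and major basic protein, Prg2, by 7.64 (SE 1.43), while Siglec5 rose by 4.25 (SE 0.80). Normal 1 was again highest, with Epx at 120 CPM against 31.6 and 34.9 CPM in normal 2 and 3. Mature neutrophil genes, 13 measured, and macrophage genes, 19 measured, had 0 calls each, also adjusted over the list alone (camera adjusted p = 0.74 and 0.73).

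Of 24 hypoxia and glycolysis genes 4 rose, 0 fell and 20 did not pass, with 5 higher adjusted over the list alone (median 1.17; camera adjusted p = 3.1e-06; adjusted p = 0.58 with an estimated correlation). Beside Vegfa these were the mitophagy gene Bnip3 (2.02, SE 0.32), the pyruvate dehydrogenase kinase Pdk1 (1.23, SE 0.31) and adrenomedullin, Adm (1.86, SE 0.47). With delayed 2 and nonunion 2 left out, 13 members rose, and 19 adjusted over the list alone. Of 13 endothelial genes 2 fell, and 4 adjusted over the list alone (7 and 11 without delayed 2 and nonunion 2; median -1.25; camera adjusted p = 0.00011; adjusted p = 0.58 with an estimated correlation). The diaphragm protein gene Plvap fell by 4.19 (SE 1.00) and the junction gene Esam by 1.22 (SE 0.30). The pericyte gene Cspg4 fell by 1.87 (SE 0.47), as 1 of 12 list members called and 5 adjusted over the list alone (camera adjusted p = 0.0071; adjusted p = 0.63 with an estimated correlation). In the angiogenic signalling list, Vegfa rose while Angpt2 (-2.08, SE 0.44) and Pdgfa (-1.54, SE 0.38) fell, with 1 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.15). Esam, Cspg4 and Pdgfa were not called with DESeq2 size factors, without the filter on low counts or without ribosomal RNA, and Pdk1 and Adm were not called without that filter or with effective lengths as offsets, nor Adm with limma-voom. Esam and Pdgfa were also not called with effective lengths as offsets. The replicate block ended the calls of Plvap, Esam, Cspg4, Pdgfa, Pdk1 and Adm. With only the groups compared in the fit, Esam, Angpt2, Adm and the neutrophil gene Ctsg were not called.

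Some signalling and matrix genes fell as well. Of 28 Wnt genes 6 fell, and 11 adjusted over the list alone (median -1.38; camera adjusted p = 1.2e-06; adjusted p = 0.28 with an estimated correlation). They included the ligand Wnt5b (-5.05, SE 0.42), the antagonist Nkd2 (-2.14, SE 0.36) and sclerostin, Sost, which had 82 reads in normal and 1 in delayed (99.8-fold lower, 95% counting interval 17.4 to 3990). Of 29 BMP and TGF-beta genes 5 fell, and 6 adjusted over the list alone (camera adjusted p = 0.0016; adjusted p = 0.44 with an estimated correlation). Among these were the pseudoreceptor Bambi (-4.91, SE 0.64), the BMP target Id3 (-3.08, SE 0.45) and the BMP antagonist Grem1 (-4.21, SE 0.73). Of 23 matrix protease and inhibitor genes 2 fell, and 6 adjusted over the list alone (camera adjusted p = 0.016; adjusted p = 0.46 with an estimated correlation). Both are proteases: the collagenase Mmp13 (-6.98, SE 0.92) and Mmp3 (-3.57, SE 0.81). The fibroblast genes Cthrc1 (-2.19, SE 0.49) and Lum (-1.93, SE 0.44) fell too, with 3 of 17 called and 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.15). Lum was not called with the replicate block or with only the groups compared in the fit, nor Mmp3 with that block.

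Some of the largest changes had no list. Klkb1, encoding plasma prekallikrein, had no reads in the 3 normal libraries and 38.5 ± 15.6 CPM (SD, n = 3) in delayed, at least 246-fold higher against 3 reads per library. It also averaged 21.5 CPM in nonunion and 19.9 CPM in preOP, with at least 14.6 CPM in every library outside normal, so the normal libraries alone lacked it. Panx3, a channel gene of bone and cartilage, fell by 10.25 (SE 0.80). Mboat7 averaged 47.0 ± 7.94 CPM in normal, 0.0781 ± 0.0768 in delayed and 0.0958 ± 0.0944 in preOP (SD, n = 3 each). Ndufa10l1 likewise had 830 reads in normal, 1 in delayed (1010-fold lower, counting interval 181 to 39900) and 0 in nonunion and preOP. Matn4, with 1 read in delayed, was 716-fold lower (128 to 28300) and Entpd3, with 2 reads, was 582-fold lower (161 to 4810). Tmem158, with no reads in delayed, was at least 66.8-fold lower against 3 reads per library. Myo5b (6.57, SE 1.36), Perm1 (6.08, SE 1.36), Sec31b (5.88, SE 0.95), Aqp4 (5.82, SE 1.36) and the non-coding Miat (4.87, SE 0.74) rose. Perm1 and Aqp4 were highest in delayed 2, at 121 and 20.2 CPM, against at most 4.68 and 1.33 CPM in delayed 1 and 3, and were not called by limma-voom, while DESeq2 gave them no adjusted p. Both lost their calls with only the groups compared in the fit, and Perm1 with the replicate block.

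Single libraries weighed on the count: 208, 268 and 175 genes were called without normal 1, 2 and 3, and 188 and 236 without delayed 1 and 3. Of the 55 called genes that the rule selects, 24 stayed called in each of 6 such fits, among them Ibsp, Bglap, Alpl, Dlx5, Mepe, Dmp1, Dkk1, Col11a2, Comp, Sox9, Np4, Epx, Bambi, Id3, Wnt5b, Mmp13, Panx3 and Klkb1, while Vegfa, Bnip3, Pdk1, Adm, Plvap, Esam, Cspg4, Lcn2, Ctsg and 22 others did not.

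Nonunion against normal asks the same of the 5.0 mm defect. The bone genes were again far lower. Ibsp averaged 3.52 ± 1.25 CPM (SD, n = 3) in nonunion and fell by 8.18 on the log2 scale (SE 0.46, edgeR adjusted p = 0.00024). Alpl, at 3.01 ± 1.45 CPM (SD, n = 3), fell by 6.78 (SE 0.56), Bglap by 6.68 (SE 0.41) and Dlx5 by 4.28 (SE 0.48). Complement factor B, Cfb, rose by 5.98 (SE 1.11), with 584 CPM in nonunion 2 against 19.9 and 103 CPM in nonunion 1 and 3. It was not called with limma-voom, with the replicate block or with only the groups compared in the fit.

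In all, 296 of 12474 genes were called, 111 higher and 185 lower in nonunion. There were 428 calls without delayed 2 and nonunion 2, of which 177 were higher, 251 lower and 248 shared with the 296.

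Of 13 osteoblast and bone matrix genes 4 fell, and 10 adjusted over the list alone (median -3.37; camera adjusted p = 1.1e-25; adjusted p = 0.0027 with an estimated correlation). Of 8 osteocyte genes 5 fell, and 6 adjusted over the list alone (median -4.25; camera adjusted p = 1e-12; adjusted p = 0.013 with an estimated correlation). Examples were Mepe (-10.14, SE 0.83), Dmp1 (-6.03, SE 1.12) and Dkk1 (-3.62, SE 0.60). Of 12 chondrocyte genes 8 fell, and 10 adjusted over the list alone (median -4.31; camera adjusted p = 3.2e-18; adjusted p = 0.02 with an estimated correlation). Among them were Col11a2 (-6.26, SE 0.57), Comp (-4.92, SE 0.51), Sox9 (-2.62, SE 0.43) and Indian hedgehog, Ihh (-4.78, SE 0.78), a signal of maturing chondrocytes. Leaving out delayed 2 and nonunion 2, the 3 lists kept an adjusted p below 0.05 with an estimated correlation (0.02, 0.038 and 0.038).

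Of 10 neutrophil granule precursor genes 5 fell, and 9 adjusted over the list alone (median -5.68; camera adjusted p = 4.1e-09; adjusted p = 0.41 with an estimated correlation). Np4 fell by 7.25 (SE 1.09) and the cathelicidin gene Camp by 5.82 (SE 1.21), with Camp at 322 CPM in normal 1 against 39.4 and 60.7 CPM in normal 2 and 3. Camp was not called with limma-voom or without delayed 2 and nonunion 2. The eosinophil genes Epx (-6.49, SE 0.87) and Prg2 (-8.63, SE 1.52) fell, with 3 of 13 list members called and, adjusted over the list alone, 4 lower and 1 higher (camera adjusted p = 0.022; adjusted p = 0.74 with an estimated correlation). Megakaryocyte and platelet genes had 0 of 7 called but 7 lower adjusted over the list alone (median -3.96; camera adjusted p = 0.00016; adjusted p = 0.46 with an estimated correlation). Normal 1 was highest, with a list median of 4.51 log2 CPM against 1.15 and 2.42 in normal 2 and 3 and 0.41 to 0.87 in nonunion. Of 17 fibroblast genes 2 fell, Cthrc1 (-3.00, SE 0.51) and Lum (-2.10, SE 0.45), and 5 adjusted over the list alone. The camera adjusted p for this list was 0.00074, and 0.57 with an estimated correlation. Lum was not called without the filter on low counts, with the replicate block or with only the groups compared in the fit. It was also not called without delayed 2 and nonunion 2.

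Of 28 Wnt genes 4 fell, and 9 adjusted over the list alone (median -0.93; camera adjusted p = 2.7e-05; adjusted p = 0.41 with an estimated correlation), with Wnt5b at -3.70 (SE 0.39) and the receptor Fzd2 at -2.83 (SE 0.56). Of 29 BMP and TGF-beta genes 3 fell, and 4 adjusted over the list alone (camera adjusted p = 0.0016; adjusted p = 0.41 with an estimated correlation), with Bambi at -3.67 (SE 0.61) and Tgfb3 at -1.49 (SE 0.29). Mmp13 fell by 7.74 (SE 0.96). Of 20 interferon response genes 1 rose, the T cell attractant Cxcl9 (4.10, SE 0.78), which was also the only 1 adjusted over the list alone (camera adjusted p = 0.12). Cxcl9 was not called with limma-voom or with the replicate block. Of 19 complement genes only Cfb was called, and 3 were higher adjusted over the list alone (camera adjusted p = 0.0069; adjusted p = 0.55 with an estimated correlation). Adipocyte genes had 0 of 11 called and 9 higher adjusted over the list alone (median 3.71; camera adjusted p = 0.0013; adjusted p = 0.74 with an estimated correlation). In nonunion 2, 9 of these 11 were at least 4-fold above every other hematoma library.

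Among changes without a list, Klkb1 was at least 137-fold higher than in normal, where it had no reads, and Ndufa10l1, with no reads in nonunion, was at least 60.6-fold lower. Panx3, with 3 reads in nonunion, was 1530-fold lower (95% counting interval 525 to 7440), Mboat7, with 2 reads, was 1390-fold lower (385 to 11500), and the globin Hba-a3, with 1 read, was 1080-fold lower (193 to 42500). The far more abundant globin Hba-a1 averaged 1600 CPM in normal and 453 CPM in nonunion, against 18.3 CPM for Hba-a3 in normal. Whether the assignment of reads among globin genes plays a part was not tested. The citrate transporter Slc13a5 fell by 9.53 (SE 0.83). Ccdc169 (5.24, SE 0.94), Cyp11b1 (5.18, SE 0.64), Smim38 (4.59, SE 0.94) and Rsph14 (4.39, SE 0.74) rose, with their highest levels among nonunion libraries in nonunion 2 (Cyp11b1 at 33.8 CPM, against 8.15 and 14.4 CPM in nonunion 1 and 3). Cyp11b1, Ccdc169 and Rsph14 averaged 0.486, 0.119 and 0.545 CPM in normal. They were higher in delayed (12.3, 4.19 and 9.84 CPM) and in preOP (7.68, 4.45 and 13.9 CPM) as well. Ccdc169, Smim38 and Rsph14 were not called with only the groups compared in the fit, nor Smim38 with limma-voom. The calls of this comparison and of delayed against normal shared 100 higher and 172 lower genes, with 0 in opposite directions, but both use the same 3 normal libraries.

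Leaving out normal 1, 2 or 3 left 38, 80 and 37 calls, and leaving out nonunion 1, 2 or 3 left 65, 158 and 23. Of the 41 called genes that the rule selects, 12 stayed called in each of 6 such fits (Ibsp, Bglap, Alpl, Mepe, Col11a2, Comp, Wnt5b, Klkb1, Ndufa10l1, Panx3, Mboat7 and Slc13a5), while Dlx5, Dkk1, Dmp1, Ihh, Sox9, Np4, Camp, Epx, Prg2, Cthrc1, Lum, Cfb, Cxcl9, Bambi, Tgfb3, Fzd2, Mmp13, Hba-a3, Ccdc169, Cyp11b1, Smim38, Rsph14 and 7 others did not.

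**Figure D4:**
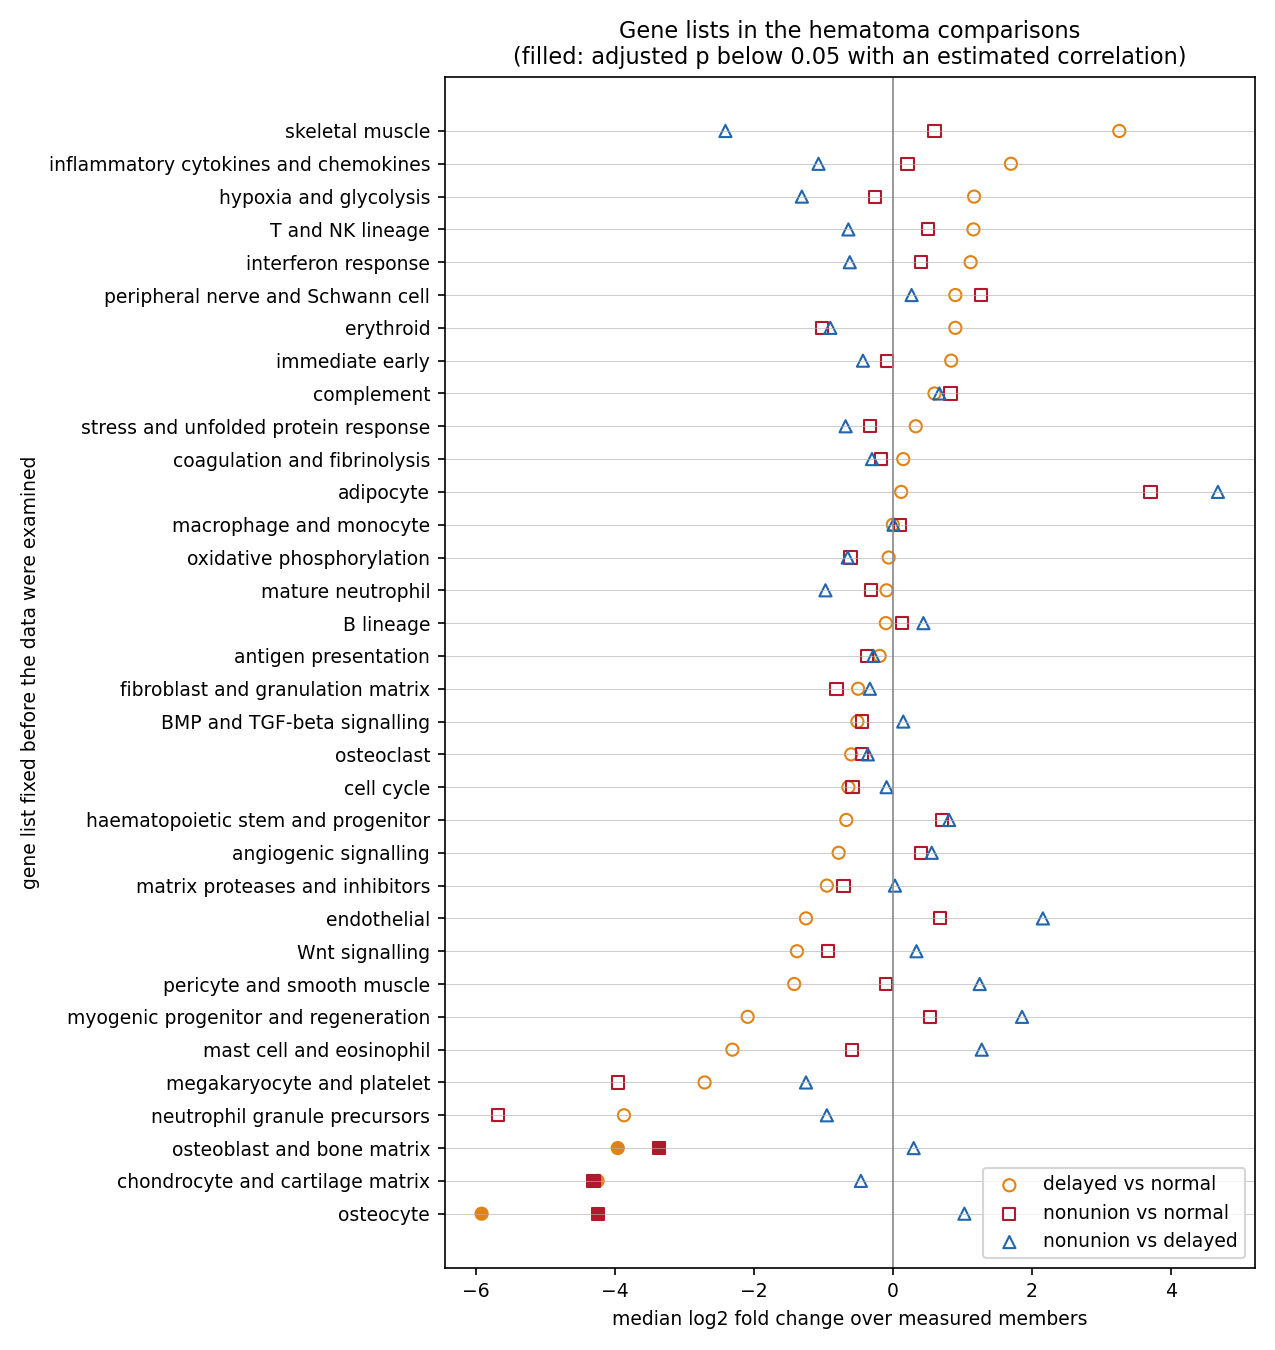
Markers show the median log2 fold change of each gene list in the 3 hematoma comparisons, filled where the adjusted p with an estimated correlation was below 0.05. Filled markers are the osteoblast, osteocyte and chondrocyte lists in delayed against normal (-3.96, -5.92 and -4.25) and nonunion against normal (-3.37, -4.25 and -4.31).

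Nonunion against delayed compares the hematomas of the 5.0 mm and 1.5 mm defects. No gene was called by edgeR, so the values that follow are differences that did not pass there. Endothelial genes leaned higher in nonunion, with 13 of 13 log2 fold changes positive and a median of 2.16, and were highest in nonunion 2. The endothelial adhesion gene Pecam1 averaged 60.7 ± 37.8 CPM in delayed and 274 ± 169 CPM in nonunion (SD, n = 3 each; 453 CPM in nonunion 2, 117 and 252 CPM in nonunion 1 and 3). Its log2 fold change was 2.13 (SE 0.55, edgeR adjusted p = 0.43), and the receptor gene Tie1 stood at 1.14 (SE 0.27, adjusted p = 0.39). Vegfa stood at -1.97 (SE 0.45, adjusted p = 0.39), with 24 of 24 hypoxia and glycolysis genes negative.

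The edgeR count was 0 of 12474 genes, with 881 at an unadjusted p below 0.05 and a smallest adjusted p of 0.36. DESeq2 called 184 genes, limma-voom 0 and limma-voom with library weights 269. After delayed 2 and nonunion 2 were left out, edgeR called 60 genes, 56 higher and 4 lower.

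Adjusted over the list alone, 12 of 13 endothelial genes were higher (camera adjusted p = 6.3e-25; adjusted p = 0.3 with an estimated correlation) and 6 of 24 hypoxia and glycolysis genes were lower (median -1.31; camera adjusted p = 4.1e-20; adjusted p = 0.3 with an estimated correlation). Of 12 pericyte genes 3 were higher in this way (camera adjusted p = 4.6e-09; adjusted p = 0.3 with an estimated correlation), and of 22 angiogenic genes 6 were higher and 2 lower (camera adjusted p = 9.1e-06; adjusted p = 0.3 with an estimated correlation). Stress and unfolded protein response genes had 4 of 15 lower (camera adjusted p = 3.5e-08; adjusted p = 0.35 with an estimated correlation). Adipocyte genes had 8 of 11 higher (median 4.68; camera adjusted p = 5.4e-07; adjusted p = 0.54 with an estimated correlation). Their values followed nonunion 2: Fabp4 stood at 2.91 (SE 0.99) and adipsin, Cfd, at 5.53 (SE 1.76), with Cfd at 2660 CPM in nonunion 2 and at most 32.9 CPM in nonunion 1 and 3. The complement gene C4b stood at 5.24 (SE 1.69), with 2820 CPM in nonunion 2. The globin Hbb stood at -2.88 (SE 0.84), with 10800 CPM in delayed 1 and at most 1450 CPM in delayed 2 and 3.

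Myogenic genes depended on the same libraries. With all 9 libraries their median was 1.86 with 0 of 10 called and 0 adjusted over the list alone (camera adjusted p = 0.00013; adjusted p = 0.54 with an estimated correlation). Without delayed 2 and nonunion 2, 5 of 10 rose, and 10 adjusted over the list alone (median 4.36; adjusted p = 0.014 with an estimated correlation), including the muscle transcription factor Myog (6.60, adjusted p = 0.039) and embryonic myosin, Myh3 (8.06, adjusted p = 0.011). The 2 libraries left out were those that went against this rise. Summed myogenic CPM was 328.1 in delayed 2, against 13.9 and 17.8 in delayed 1 and 3. It was 22.7 in nonunion 2, against 418.3 and 851.7 in nonunion 1 and 3. The rise and its p-values thus follow from that choice, with 2 libraries left per group, and establish no difference. With all libraries Myog stood at 4.02 (SE 1.67) and Myh3 at 1.15 (SE 1.95), with Myh3 at 144 CPM in delayed 2 and at most 0.653 CPM in delayed 1 and 3. The adult fast myosin Myh2 stood at -6.65 (SE 2.83) with all libraries and at 4.15 without those 2, since delayed 2 carried it at 9600 CPM.

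The mean hematoma against preOP sets the hematomas of all 3 defect sizes against femur removed at surgery. Genes of marrow blood formation were far lower in hematoma. The red cell blood group gene Rhag averaged 417 ± 83.0 CPM in preOP and 1.32 ± 1.15, 0.767 ± 0.536 and 0.341 ± 0.243 CPM in normal, delayed and nonunion (SD, n = 3 each), and fell by 9.29 on the log2 scale (SE 0.58, edgeR adjusted p = 1.8e-06). The proliferation gene Mki67 fell by 3.45 (SE 0.31), from 1870 ± 168 CPM in preOP (SD, n = 3). The macrophage gene Gpnmb rose by 4.60 (SE 0.61), the collagen gene Col3a1 by 3.84 (SE 0.60) and the monocyte attractant Ccl7 by 8.04 (SE 0.89).

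In all, 5212 of 12846 genes were called, 2262 higher and 2950 lower in hematoma. Which direction held more genes depended on the setting, with 2805 higher and 2461 lower without ribosomal RNA and 3048 and 2788 in DESeq2. Against each hematoma group alone, 5466 genes were called for normal (2630 higher), 3622 for delayed (1615 higher) and 3649 for nonunion (1736 higher). With the normal libraries and their other file format left out, the count was 4202, with 3861 shared. It was 7276 without delayed 2 and nonunion 2, with 5004 shared.

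All 18 erythroid genes fell, as did 18 adjusted over the list alone (median -6.59; camera adjusted p = 9.9e-30; adjusted p = 0.11 with an estimated correlation), including Rhag and the membrane skeleton gene Epb42 (-6.73, SE 0.34). Globin reads were 15.66% to 23.98% in preOP. Also fallen were 8 of 8 megakaryocyte genes (camera adjusted p = 4.4e-08; adjusted p = 0.23 with an estimated correlation) and 13 of 13 mast cell and eosinophil genes (camera adjusted p = 4.4e-08; adjusted p = 0.23 with an estimated correlation), with the same counts adjusted over the list alone. Examples were the platelet genes Ppbp (-7.60, SE 0.64) and Gp9 (-6.75, SE 0.65), and the IgE receptor gene Ms4a2 (-6.52, SE 0.82). Of 11 neutrophil granule precursor genes 10 fell, and 11 adjusted over the list alone (camera adjusted p = 5.1e-07; adjusted p = 0.26 with an estimated correlation), with Ngp at -7.09 (SE 0.76). Of 12 B lineage genes 10 fell, and 11 adjusted over the list alone (camera adjusted p = 5.1e-07; adjusted p = 0.23 with an estimated correlation), with the recombinase gene Rag1 at -7.92 (SE 0.66). Of 21 cell cycle genes 19 fell, and 20 adjusted over the list alone (camera adjusted p = 1.9e-06; adjusted p = 0.53 with an estimated correlation).

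Of 19 macrophage and monocyte genes 12 rose, and 12 adjusted over the list alone (median 1.50; camera adjusted p = 5.9e-05; adjusted p = 0.39 with an estimated correlation), with the lipid receptor gene Trem2 at 5.26 (SE 0.71) and Cd14 at 3.61 (SE 0.48). Of 17 fibroblast and granulation matrix genes 12 rose, and 14 adjusted over the list alone (median 2.57; camera adjusted p = 5.1e-07; adjusted p = 0.23 with an estimated correlation), among them Pdgfra (2.44, SE 0.26) and Cthrc1 (2.86, SE 0.42). Of 23 matrix protease and inhibitor genes 14 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 2e-06; adjusted p = 0.062 with an estimated correlation). The inhibitor Timp1 rose by 4.78 (SE 0.56) and the aggrecanase Adamts4 by 4.16 (SE 0.51). Of 24 hypoxia and glycolysis genes 20 rose and 1 fell, with 21 and 1 adjusted over the list alone (median 1.90; camera adjusted p = 4e-07; adjusted p = 0.39 with an estimated correlation), with Adm at 4.11 (SE 0.45) and P4ha2 at 3.70 (SE 0.50). Of 22 cytokine and chemokine genes 12 rose and 1 fell, with 13 and 1 adjusted over the list alone (camera adjusted p = 0.0003; adjusted p = 0.58 with an estimated correlation), including Il6 (6.57, SE 1.30). Of 15 stress genes 8 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0018; adjusted p = 0.47 with an estimated correlation), with the heat shock gene Hspa1a at 3.25 (SE 0.40) and Hmox1 at 2.28 (SE 0.42). Arginase 1, Arg1, rose by 7.73 (SE 1.24).

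Bone genes split. Of 13 osteoblast and bone matrix genes 4 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.2), with Col1a2 at 2.32 (SE 0.45) and Bglap at -5.74 (SE 0.22). For Ibsp (-2.80, SE 0.24) and Mepe (-3.17, SE 0.42) the mean joins groups on opposite sides of preOP. Ibsp averaged 158 ± 50.6 CPM in preOP (SD, n = 3), below normal and above delayed and nonunion. Of 13 osteoclast genes 4 rose and 3 fell (camera adjusted p = 0.44), with Ctsk at 2.73 (SE 0.43) and the carbonic anhydrase gene Car2, which red cells also carry, at -6.95 (SE 0.50). Adjusted over the list alone, 5 were higher and 3 lower.

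With the 9 hematomas as 1 group the count was 4083 and Ibsp and Mepe took positive values (1.06 and 1.53), while Bglap was not called. DESeq2 gave no adjusted p for Ngp (-6.98). Of the 131 called genes the rule selects, 121 stayed called in each of 12 fits without 1 library, and 10 others (Dmp1, Chrna1, Myog, Myod1, Myf5, Cd27, Cxcl10, Tap1, RT1-DMa and RT1-DMb) did not.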

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

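Of the tests in this part, only the one on ribosomal protein genes was chosen before its result was seen. Its bootstrap spread and its other measure of spread, and the thresholds for genes that part 1 group from all others, were added afterwards.

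Genes drew attention where normal and another hematoma group moved to opposite sides of preOP, with both moves called and the difference between the hematoma groups tested in edgeR (adjusted p of 0.00022 to 0.032). For delayed against normal these were Alpl (difference -6.71; normal 2.95 and delayed -3.73 against preOP), Bambi (-4.91; 2.58 and -2.30), Comp (-4.62; 2.85 and -1.73), Dlx5 (-5.82; 1.92 and -3.89), Dmp1 (-7.55; 2.62 and -4.87), Entpd3 (-8.90; 2.67 and -6.21) and Ibsp (-8.24; 2.64 and -5.57). The others were Irx5 (-5.73, 3.28 and -2.41), Matn4 (-8.95, 3.11 and -5.82), Mepe (-8.79, 3.11 and -5.65), Mmp13 (-6.98, 5.01 and -1.94), Panx3 (-10.25, 7.68 and -2.53), Wnt5b (-5.05, 2.31 and -2.73) and, the other way round, Miat (4.87, -3.05 and 1.81). For nonunion against normal the differences and the values of nonunion against preOP were Alpl -6.78 and -3.76, Comp -4.92 and -1.99, Dlx5 -4.28 and -2.30, Dmp1 -6.03 and -3.33, Hba-a3 -9.65 and -7.14, Ibsp -8.18 and -5.47, Mepe -10.14 and -6.96, Mmp13 -7.74 and -2.64, Panx3 -10.41 and -2.66, Slc13a5 -9.53 and -6.14, and Wnt5b -3.70 and -1.33. Normal stood 2.45 above preOP for Hba-a3 and 3.33 for Slc13a5. The globins Hba-a1 and Hbb went the other way, at 1600 and 1360 CPM in normal against 57000 and 77700 CPM in preOP. Entpd3 and Matn4 in delayed and Hba-a3 and Panx3 in nonunion had 1 to 3 reads, so their fitted values depend on the prior count.

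In all, 21 osteoblast, osteocyte and chondrocyte genes were called lower in delayed than in normal. Femur pieces like the preOP samples, mixed into normal hematomas, would raise these genes alike where the hematoma itself holds little of them. The log2 ratio of normal to preOP instead had an SD of 1.56 over the 21 genes against a median SE of 0.603. Without Sost, which had 1 read in preOP, the SD was 1.42 against 0.586 (-1.55 for Bglap to 5.23 for Hapln1). Such pieces alone would not lift normal above preOP. Yet in 19 of the 21 genes every normal library stood above every preOP library, and in 1 gene every one stood below. These values argue against such pieces as the whole cause. The 21 genes were chosen as higher in normal than in delayed, which favours high values in normal. Bone with less marrow than the preOP pieces, which carried 15.66% to 23.98% globin reads, is not covered by this test. With effective lengths as offsets 21 of 21 genes stayed called, while 179 other calls were lost. The median gap between length and effective length was 157.2 to 191.6 bases in normal and 194.3 to 254.6 elsewhere. Offsets from such gaps are small beside the changes of these genes, so they could not remove the calls. This test therefore does not decide on a difference in fragment length. A library preparation or processing batch of the normal libraries cannot be told apart from defect size, because 0 libraries of other groups had the number format of the normal files. The biological difference, defect size, stays open as untested.

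In all, 36 of 10466 genes with a mean of at least 5 CPM parted the 3 normal libraries from all 9 others by 4-fold or more (29 higher and 7 lower), against 0 for delayed, 0 for nonunion and 248 for preOP (by chance 0.9% of genes part 3 libraries from 9, at any fold). That share has no fold threshold, so it does not tell whether 36 is more than chance gives. No explanation was excluded. A batch of the normal libraries was predicted to spread ribosomal protein genes more in comparisons with normal. Rpl36 was left out, because it had been seen. The lowest SD with normal (0.488) was in fact below the highest without it (0.526), but by 0.038 against a bootstrap SD of 0.17. The median absolute deviations ran the other way (0.354 with and 0.271 without). The median log2 fold changes were 0.96 to 1.11 with normal and -0.13 to -0.01 without. A batch that moved these genes together would shift the medians and leave the SD as it was, so the SD cannot decide. Batch and defect size cannot be told apart here. Strain or substrain variants stay open as well: 4 of 26 RT1 genes (RT1-A2, RT1-CE10, RT1-CE11 and RT1-CE2) were among the 36 (Fisher's exact p = 1.7e-06, odds ratio 58.9), but the test was run because they had been seen there, with its background narrowed after a first run, so the p restates that observation and supports no explanation, and RT1 paralogs share reads. Defect size also stays open as untested.

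Libraries nonunion 2 and delayed 2 stood apart from the other hematoma libraries. Dilution of an otherwise like nonunion library by ribosomal RNA is argued against, since without ribosomal RNA, and with the other libraries thinned to its total of 4.77 M (1e6) reads, nonunion 2 correlated with nonunion 1 or 3 at 0.833 at most, against 0.956 between those. Adipose tissue is a candidate source in nonunion 2, where 9 of 11 adipocyte genes were at least 4-fold above every other hematoma, with Fabp4 at 4430 CPM (highest other 508) and Cfd at 2660 CPM (highest other 66.1), although 7 of the 11 exceeded 1 CPM in every other hematoma and 1 is on another list. Skeletal muscle fibres are a candidate source in delayed 2, with 18 of 20 muscle genes so raised, Acta1 at 11600 CPM (highest other 2190) and Myh2 at 9600 CPM (highest other 75.3), although 17 of the 20 exceeded 1 CPM in every other hematoma and 0 are on another list. If such tissue was present, whether it was picked up at sampling or differed between the animals stays open. Beyond dilution, an effect of RNA or library quality in nonunion 2, with 72.17% of reads on ribosomal RNA, was not tested.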

How the results depend on the processing

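The fits with library weights in voom, without delayed 2 and nonunion 2, without ribosomal RNA, with effective lengths as offsets, with robust = TRUE and without the normal libraries were chosen after seeing the data, the others before the data were examined. Where a count moved, the cause was not tested.

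For delayed against normal (889) and nonunion against normal (296), the replicate block left 433 and 148 calls, DESeq2 gave 2033 and 1310, voom with library weights 4062 and 2279, and a fit of all 12 libraries 1820 and 992. Leaving out delayed 2 and nonunion 2 gave 2056 calls for the former. For nonunion against delayed (0 in edgeR, 881 at an unadjusted p below 0.05), DESeq2 called 184, voom with library weights 269, limma-voom 0 and the fit without those 2 libraries 60. Against preOP, library weights gave 9584 calls for the mean hematoma, 9480 for normal, 7644 for delayed and 7517 for nonunion. Other alternatives stayed within 1.5 times the counts reported. The share of higher genes in nonunion against normal (37.5%) was 20.2% with only the groups compared, 50.8% with DESeq2 and 36 of 148 genes with the replicate block, and ran from 10.8% (without normal 3) to 55.4% (without nonunion 1) leaving out 1 library. For delayed against normal (37.6%) it was 21.2% without normal 1 and 18.3% without normal 3. Without ribosomal RNA it went from 43.4% to 53.3% for the mean hematoma, 44.6% to 57.5% for delayed and 47.6% to 57.2% for nonunion against preOP.

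Gene lists called by camera (15, 15, 18 and 13 of 34) numbered 3, 3, 0 and 0 with an estimated correlation and 6, 3, 0 and 17 with fry.

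Leaving out 1 library at a time gave 175 (without normal 3) to 726 calls (without delayed 2) for delayed against normal, 23 (without nonunion 3) to 158 (without nonunion 2) for nonunion against normal and 0 to 1 for nonunion against delayed (1 without delayed 2 or nonunion 2). Against preOP the ranges were 3568 to 6160 for the mean hematoma, 3952 to 4846 for normal, 2292 to 4030 for delayed and 2334 to 4221 for nonunion, each lowest without preOP 2. Delayed fell to 2303 without preOP 3, and nonunion to 2425 without preOP 1 and 2415 without preOP 3. List counts ran from 15 to 18, 12 to 19, 13 to 22 and 13 to 17.

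Over all named genes and alternatives, 4613 values kept direction and side of the threshold, 423 fell short of it, 8 newly passed and 8 reversed. Myh2 in nonunion against delayed (-6.65) took 1.54 with library weights, 4.15 without delayed 2 and nonunion 2, and -8.34 to 3.85 (without delayed 2) leaving out 1 library. Myh3 (1.15) ran from -0.37 (without nonunion 3) to 7.47 (without delayed 2). Cfd (5.53) took -0.03 without delayed 2 and nonunion 2. With all hematomas as 1 group against preOP, Ibsp, Mepe and Dmp1 took 1.06, 1.53 and 1.07 (-2.80, -3.17 and -1.86 in the mean of groups), since a plain mean gives weight to the high normal group.

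Without ribosomal RNA the median of all genes moved by 0.17 for the mean hematoma, 0.13 for normal, 0.21 for delayed and 0.16 for nonunion against preOP, and with DESeq2 size factors by 0.13 for delayed. At most 2 of 34 list medians per comparison changed sign with either scaling. Quantile scaling and a smaller pseudocount, planned for normalized values, did not apply to counts. In nonunion 2, 4.77 M (1e6) reads outside ribosomal RNA and 2 unnamed transcripts linked to it limit what can be seen, with 3 reads at 0.46 CPM.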

Other observations

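Genes of muscle regeneration were higher in hematoma than in preOP in some libraries. Of 10 myogenic genes 4 rose in the mean hematoma and 0 fell, with 4 higher adjusted over the list alone (median 2.59; camera adjusted p = 0.08). Myog rose by 5.46 (SE 1.60, edgeR adjusted p = 0.019) and stood at 43.9 to 169 CPM in normal, 1.27 to 23.9 in delayed and 0.462 to 318 in nonunion. The 4 calls (Chrna1, Myog, Myod1 and Myf5) were lost in each of 3 fits without 1 preOP library, limma-voom did not call Myog, Myod1 or Myf5, and Chrna1, Myod1 and Myf5 were not called without the normal libraries. Among nerve and Schwann cell genes, 2 of 10 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.79). The receptor Erbb3 rose by 4.69 (SE 0.62) and the adhesion gene Ncam1 by 2.96 (SE 0.76), while the myelin gene Mbp (-2.18, SE 0.53) fell. Mbp stood at 39.9 CPM in nonunion 2, close to its preOP levels, and was not called without the normal libraries.

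Interferon response and antigen presentation genes went both ways against preOP. Of 20 interferon genes 3 rose and 3 fell, with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.96). The antiviral gene Rsad2 averaged 742 ± 175 CPM in preOP and 13.6 ± 10.3, 47.4 ± 26.2 and 7.36 ± 4.41 CPM in normal, delayed and nonunion (SD, n = 3 each), a fall of 5.46 on the log2 scale (log2 fold change -5.46, SE 0.47, edgeR adjusted p = 1.4e-05). Irf9 fell (-1.81, SE 0.21) while Ifi27 rose (1.26, SE 0.28). Of 15 antigen presentation genes 2 rose and 2 fell, with 1 and 2 adjusted over the list alone (camera adjusted p = 0.98). The class I transporter genes Tap2 (-1.43, SE 0.28) and Tap1 (-0.99, SE 0.28) fell, and the class II genes RT1-DMa (1.77, SE 0.55) and RT1-DMb (1.22, SE 0.43) rose. Tap1, RT1-DMa and RT1-DMb were not called without the normal libraries, nor in any of the 3 fits without 1 preOP library, and RT1-DMb (1.14) was not called with the replicate block.

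The tests on other splits of the samples were chosen before the data were examined, and the comparison with simulated shared controls was chosen after the calls were seen. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split was the only 1 of 10 to reach its count of genes for delayed against normal (889, highest other 0), nonunion against normal (296, highest other 0), normal against preOP (5466, highest other 0), delayed against preOP (3622, highest other 0) and nonunion against preOP (3649, highest other 0). For nonunion against delayed 10 of 10 splits reached the edgeR count of 0 (highest other 2), as any split must, so this says nothing about chance. In that comparison 881 genes had an unadjusted p below 0.05, and DESeq2 called 184. For all hematomas as 1 group against preOP, 1 of 100 splits reached 4083 genes (highest other 3), a share under 0.05. The other splits were a random draw that did not hold the 3 normal libraries against the rest, and separate animals are not established. The splits drawn thus argue against chance there but do not exclude it. Camera list counts were less particular to the real split: 6 of 10 splits reached 15 lists for delayed against normal (highest other 21), 7 of 10 reached 15 for nonunion against normal (highest other 23), and 5 of 10 reached 18 for nonunion against delayed (highest other 20). For hematoma against preOP 85 of 100 splits reached 12 lists (highest other 23), so chance cannot be excluded for that count.

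Delayed and nonunion against normal shared 100 higher and 172 lower genes, with 0 in opposite directions. The correlation of the log2 fold changes was 0.722, against 0.496 on average in 20 simulated sets with the shared normal libraries and no group differences, and 79.4% against 66.6% had the same sign. The 3 normal libraries cannot be divided into separate controls, so how much of the sharing they bring is not known.

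The numbers in the titles do not appear to pair the libraries. Over 18 pairs with the same number, the correlation of deviations from the group mean ran from -0.182 to 0.187, with 4 above 0.1, and 0 libraries matched best with their own number in every other group.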
